A study of Homo sapiens with 62 samples.

How the data were processed

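RNA from primary chronic lymphocytic leukaemia (CLL) cells was measured on 62 Affymetrix expression arrays with 54675 probe sets each. The cells came from the peripheral blood (PB), the bone marrow (BM) or a lymph node (LN) of 24 patients. Samples were grouped by the origin that the labels give, and the patient number in the labels paired the samples. Total RNA was labelled with biotin, per the labels' protocols. Whether and how CLL cells were separated from other cells is not given in the sources used here.

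The deposited table holds 1 value per probe set and array. MAS5 is the only program that the submitters' processing notes name, without a version. The deposited values are read here as log10 signal, which is an inference from the values. They ran from 0 to 4.80 with a median of 0.773 on each array. The mean values of the spiked hybridization controls rose with a slope of 1.05 per log10 unit of amount over 1 set of probe sets and 0.876 over the other, close to 1 as log10 values should. All 62 arrays held the same set of values once sorted, so the deposited values had been quantile normalized. The transform, the quantile step and any filter are not described in the labels, and the log base, the lowest value of 0 and hence every fold change rest on this inference. A quantile normalization forces equal overall distributions, so a change of total RNA per cell cannot be seen in these values.

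Values were multiplied by 3.32 to give a log2 scale. Every value below the 20th percentile of the table (0.428 as deposited) was set to that percentile, which applied to 18.9% of the values of probe sets with a gene symbol, so changes of dim genes are understated. GEO's platform annotation gave 41097 probe sets 1 symbol, 1801 several and 11777 none. Symbols were updated through the Entrez identifier for 41043 of the first kind, and no gene was named from a probe set with several. Each of the 19775 genes was represented by its probe set with the highest mean, and the 13034 genes whose mean reached the 40th percentile of all probe set means were tested. No genome build is named in the sources used here, so no coordinates are given. Of the 195 named genes and comparisons, 95 had further probe sets above the same limit. In 11 at least 1 of these went the other way, and in 2 (OAS2 and ATP5F1C) it did so with an unadjusted p under 0.05. No columns of the table were left unused.

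Pairs were formed within patients: 17 for LN and PB, 19 for BM and PB and 12 for LN and BM. The 2 PB arrays of 2 patients were averaged. Paired differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The pairing comes from the patient numbers in the labels. The deviations of same-numbered samples from their group means correlated between 0.532 and 0.746 for LN and PB, between 0.547 and 0.804 for BM and PB, and between 0.533 and 0.749 for LN and BM. Among the paired samples, every LN sample correlated best with the PB and the BM sample of its own number. Every paired BM sample correlated best with the PB sample of its own number. The reverse search was not made.

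For 25 gene lists, fixed from textbook knowledge before the data were examined, camera from limma compared the paired differences of a list with those of all other genes. Its preset inter-gene correlation of 0.01 was used, with an estimated correlation as the alternative and adjustment over the 25 lists of a comparison. Camera's adjusted p is the one printed beside a list count unless another test is named. A list score is the mean log2 value of a list's tested members in a sample. Its paired differences were tested with a two-sided sign-flip permutation test of 100000 resamples, adjusted in the same way. Small lists of other cell types often lost members to the limit on dim genes. Of the T cell markers 7 of 16 were tested, and of the tissue macrophage markers 3 of 12.

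The genes named were set by a rule before the data were examined. Per comparison, it takes the 14 largest increases and the 10 largest decreases among genes past the threshold that moved the same way in at least 75% of patients. It adds up to 4 members of each list with the smallest p in LN against PB, and the same in BM against PB for lists past the threshold there. Sex-linked marker genes, immunoglobulin and T cell receptor segments and probe sets without a single symbol were left out. A microRNA gene and an antisense RNA that the rule took are not reported here, because a gene symbol alone does not tie a probe set to those products. Genes outside the rule are said to be so where they appear.

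The procedure was tested on simulated data with 50 genes changed at each of 4 sizes. These were independent normal values that took only each gene's SD from the real paired differences. For LN and PB, 68% of genes changed by 0.5 on the log2 scale were recovered and 100% of those changed by 1. For BM and PB the shares were 90% and 100%, and for LN and BM 74% and 98%. At most 12 unchanged genes were called in any comparison. The simulation held no correlation between genes, so these shares and false calls need not carry over to the real data.

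Alternatives changed the floor, the limit on dim genes, the choice of probe sets, the centring of arrays, the variance model, the block and the patients, or added paired differences of T cell and monocyte markers, of a handling-stress list or of the 3' to 5' control ratio as covariates. A further 3, added after the data had been seen, were leaving out the patient of the 1 LN sample whose median correlation with the others (0.909) lay below Tukey's lower fence (0.923), using the patients whose arrays show poly-A control transcripts, and erythroid and granulocyte marker differences as covariates. The poly-A controls, RNAs spiked in before labelling, were low on the arrays of 5 patients (13 samples after averaging), which is treated as a difference in labelling batch. Samples were split at the largest gap in their mean control values, between 0.991 and 1.26 as deposited. These 5 patients are called without poly-A controls below, though the values show low signal and not absence. All samples of a patient lay on the same side, so the pairing removes a batch shift. The number of arrays limits the precision, and the random block used duplicateCorrelation with statmod 1.5.0. Values were read with the R package data.table, version 1.17.8, and figures drawn with matplotlib 3.10.9.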

Results

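Gene expression was measured in CLL cells taken from the blood, the bone marrow and lymph nodes of the same patients. CLL is a leukaemia of mature B cells that circulate in the blood and also occupy marrow and lymph nodes. The 62 arrays comprised 26 of PB from 24 patients, 19 of BM from 19 patients and 17 of LN from 17 patients. All 3 compartments were sampled in 12 patients, LN and PB only in 5, and BM and PB only in 7. The series title asks about B-cell receptor (BCR) signalling, NF-κB activation and proliferation in the lymph node. The design text names LN against PB and BM against PB as matched pairs, and LN against BM asks whether the compartments differ. Repeat PB arrays of 2 patients differed with an SD over genes of 0.353 and 0.434 on the log2 scale. Arrays of different patients differed in PB by a median SD of 0.655. Paired samples of 1 patient differed by a median SD of 0.454 for LN and PB, 0.381 for BM and PB and 0.458 for LN and BM. The spread within pairs was thus near that of repeat arrays.

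In the LN, genes of cell division, of the early response to receptor stimulation and of the cellular stress response were higher than in the blood of the same patients. The largest increase was that of RGS1, a regulator of G-protein signalling in B cells, which was higher by 4.85 ± 0.39 (log2, SE, n = 17), or 28.7-fold, in 17 of 17 patients. FOS and FOSB, subunits of the transcription factor AP-1, were higher by 4.46 ± 0.30 and 3.90 ± 0.27. TYMS, the enzyme that makes thymidylate for DNA synthesis, was higher by 3.27 ± 0.21. HBB, the beta chain of haemoglobin, fell by 3.04 ± 0.36 in 17 of 17 patients. Over all genes tested, 3341 of 13034 differed between LN and PB (limma, adjusted p under 0.05), 1644 of them higher in LN and 1697 lower. At least a doubling was seen for 103 and at least a halving for 11.

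Of the 30 members of the G2/M and mitosis list, 29 rose and 1 fell (adjusted p = 4.31e-32, and 0.0458 with an estimated correlation). The same 29 and 1 were called when adjusted over the list alone. MELK, a kinase of dividing cells, was higher by 2.18 ± 0.14, TOP2A, which untangles replicated DNA, by 2.18 ± 0.17, ASPM, a spindle protein, by 1.96 ± 0.16 and CENPF, a kinetochore protein, by 1.62 ± 0.14. CDK1, the kinase that starts mitosis, was higher by 2.41 ± 0.24. The member that fell was CCNB2, a mitotic cyclin, at -0.39 ± 0.11. It was singled out after its values were seen, because its probe sets disagreed. The probe set used was the brightest of 3, and the others gave 1.87 ± 0.85 (SD, n = 17), higher in 17 of 17 patients, and -0.66 ± 0.46 (SD). In the DNA replication and E2F list, 22 of 26 members rose and none fell (adjusted p = 4.28e-17, and 0.112 with an estimated correlation, where the call is lost). Adjusted over the list alone, 23 rose. RRM2, a subunit of ribonucleotide reductase, was higher by 2.63 ± 0.22, UHRF1, which maintains DNA methylation, by 1.77 ± 0.18 and ZWINT, a kinetochore protein, by 1.69 ± 0.17. PCLAF, a factor bound to the replication clamp PCNA, was higher by 2.93 ± 0.23. The mean of the G2/M list was higher in 17 of 17 patients, by 1.31 ± 0.54 (SD, n = 17). In 4 patients whose arrays had low poly-A controls it was higher by 1.19 ± 0.11 (SD), and in the 13 others by 1.34 ± 0.62 (SD). For the replication list these values were 0.81 ± 0.06 and 0.84 ± 0.49 (SD).

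Genes that rise after engagement of the BCR were also higher in LN. Of the 22 tested members of this list, 16 rose and none fell (adjusted p = 3.87e-12, and 0.0149 with an estimated correlation), and 17 rose when adjusted over the list alone. CD83 and CD69, surface markers of activated lymphocytes, were higher by 1.65 ± 0.12 and 1.72 ± 0.16. CCL4, a chemokine that attracts T cells and monocytes, was higher by 2.36 ± 0.24, and EGR1, a transcription factor of the first minutes after stimulation, by 2.58 ± 0.34. The list mean was higher by 1.07 ± 0.37 (SD, n = 17) in 17 of 17 patients. It was higher by 1.11 ± 0.45 (SD) in the 4 patients without poly-A controls and by 1.06 ± 0.37 (SD) in the 13 others. Components of the BCR pathway went both ways, with 6 of 20 higher and 4 lower (adjusted p = 0.694), and 6 and 5 when adjusted over the list alone. The median of its members was -0.02 and their mean 0.09. CR2, a co-receptor for complement, was higher by 1.85 ± 0.13 and BLNK, the adaptor behind the receptor, by 0.29 ± 0.05. PRKCB, a kinase of the pathway, fell by 0.30 ± 0.05.

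The list of immediate early and handling-stress genes, which respond within minutes to cell disruption and to receptor signals alike, was higher in LN as well. Of its 18 tested members 15 rose, also when adjusted over the list alone, and none fell (adjusted p = 2.27e-12, and 0.0366 with an estimated correlation). DUSP1, a phosphatase of stress kinases, was higher by 2.49 ± 0.28 and NR4A2, an inducible nuclear receptor, by 2.25 ± 0.31. The list mean was higher by 1.30 ± 0.56 (SD, n = 17) in 17 of 17 patients. It was higher by 1.39 ± 0.88 (SD) in the 4 patients without poly-A controls and by 1.27 ± 0.47 (SD) in the 13 others. No member is shared with the BCR response list.

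NF-κB target genes went both ways. Of 26 tested members 9 rose, 3 fell and 14 did not pass, and the list did not pass camera (adjusted p = 0.0533, and 0.263 with an estimated correlation). Adjusted over the list alone, 9 rose and 5 fell. Leaving out each patient in turn gave 2 to 5 members that fell. CCND2, a cyclin of the G1 phase, was higher by 1.25 ± 0.09, GADD45B, a stress-induced signalling protein, by 1.32 ± 0.18, ICAM1, an adhesion molecule, by 0.68 ± 0.10 and the cytokine TNF by 0.70 ± 0.11. NFKBIA, the inhibitor that NF-κB induces, fell by 0.51 ± 0.13. It is outside the naming rule and was chosen after its values were seen. The list mean was nevertheless higher in 16 of 17 patients, by 0.18 ± 0.13 (SD; permutation test, adjusted p = 0.000188). It was higher by 0.15 ± 0.08 (SD) in the 4 patients without poly-A controls and by 0.19 ± 0.15 (SD) in the 13 others.

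**Figure D1:**
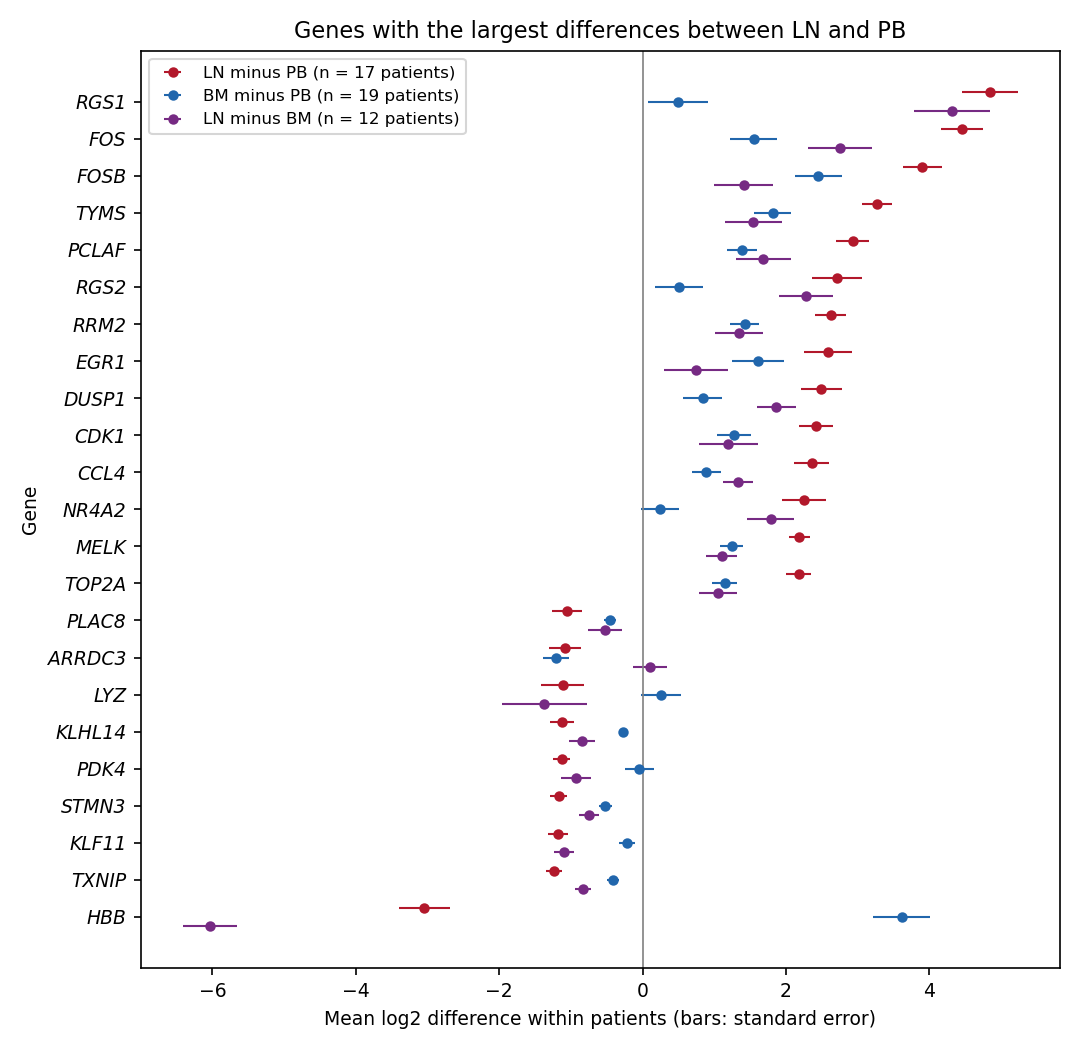
Mean log2 difference within patients (x axis) for the genes (y axis) with the largest increases and decreases between LN and PB, shown for LN minus PB (17 patients), BM minus PB (19) and LN minus BM (12). Points are means and bars standard errors. RGS1 lies at 4.85 for LN minus PB and at 0.49 for BM minus PB, and HBB lies at -3.04 and 3.61.

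Lists of MYC targets, of glycolysis and of the unfolded protein response shifted upward in LN as well, while oxidative phosphorylation did not pass camera (adjusted p = 0.120). Of 19 MYC target and ribosome biogenesis genes 10 rose (adjusted p = 1.41e-07, and 0.195 with an estimated correlation), among them NME1, a nucleotide kinase, by 1.30 ± 0.15, RRP12, a ribosome assembly factor, by 2.04 ± 0.27 and HSPD1, a mitochondrial chaperone, by 0.84 ± 0.09. Of 17 glycolysis and hypoxia genes 8 rose (adjusted p = 4.28e-05, and 0.195 with an estimated correlation), including HK2, the first enzyme of glycolysis, by 0.76 ± 0.10 and the glucose transporter SLC2A3 by 1.13 ± 0.17. Of 18 genes of the unfolded protein response 7 rose (adjusted p = 0.00556, and 0.263 with an estimated correlation), including the chaperone HSPA5 by 0.53 ± 0.07. Adjusted over each list alone the counts were 10, 9 and 7. In none of these 3 lists did a member fall.

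Among the genes with the largest decreases in LN, TXNIP, an inhibitor of glucose uptake, fell by 1.23 ± 0.11, and PDK4, which restrains pyruvate oxidation, fell by 1.13 ± 0.12, both in 17 of 17 patients. The transcription factor KLF11 fell by 1.18 ± 0.13, STMN3, a regulator of microtubules, fell by 1.17 ± 0.11, KLHL14 fell by 1.12 ± 0.17, ARRDC3, an arrestin family member, fell by 1.08 ± 0.22 and PLAC8 fell by 1.06 ± 0.21. In the list of homing receptors and adhesion, 6 of 18 rose and 4 fell (adjusted p = 0.288), and 8 rose and 4 fell when adjusted over the list alone. S1PR1, the receptor that guides lymphocytes out of lymph nodes, fell by 0.60 ± 0.12, and KLF2, its activator, fell by 0.84 ± 0.16. In the BCL2 family list 2 of 14 rose and 5 fell (adjusted p = 0.172), in the same numbers when adjusted over the list alone. BMF and BCL2L11, which promote cell death, fell by 0.73 ± 0.09 and by 0.34 ± 0.07, and BCL2, which opposes it, fell by 0.43 ± 0.07. For BCL2L11 and BCL2 these falls hold for the probe set used. Of their further probe sets above the limit on dim genes, 3 of 6 for BCL2L11 and 2 of 3 for BCL2 went the other way. None of those reached an unadjusted p under 0.05. Of 15 B cell and CLL markers 3 rose and 5 fell (adjusted p = 0.258), and 3 rose and 6 fell when adjusted over the list alone. CD5, a surface marker of CLL, fell by 0.44 ± 0.09 and TCL1A, a kinase co-activator, fell by 0.41 ± 0.06.

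Markers of other cell types differed between LN and PB too. Of 7 tested T cell markers 4 rose, and as many when adjusted over the list alone (adjusted p = 0.0200, and 0.263 with an estimated correlation), led by CD3D, a chain of the T cell receptor complex, at 0.80 ± 0.17. Of 7 erythroid markers 3 fell, and as many when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0533, and 0.263 with an estimated correlation). The erythroid mean was nevertheless lower in 17 of 17 patients, at -0.63 ± 0.51 (SD; permutation test, adjusted p = 0.000125). It was -0.51 ± 0.60 (SD) in the 4 patients without poly-A controls and -0.67 ± 0.49 (SD) in the 13 others. Of 12 monocyte markers 1 rose and 3 fell (adjusted p = 0.296), with LYZ, lysozyme, lower by a log2 value of -1.11 ± 0.30. Adjusted over the list alone, 2 rose and 5 fell, and leaving out each patient in turn gave 2 to 5 that fell. The log2 ratio of 3' to 5' probe sets, a measure of RNA degradation, differed by 0.15 ± 0.34 (SD, n = 17) for ACTB and by -0.05 ± 0.26 for GAPDH (permutation test, adjusted p = 0.272 and 0.554). Without the patient block 1050 genes were called, and the count was 2223 in the 12 patients with all compartments, 1107 with T cell and monocyte differences as covariates, 382 with erythroid and granulocyte differences and 75 with the handling-stress difference. Under that last covariate 0 of 22 BCR response members were called by limma (9 had an unadjusted p under 0.05) and 15 of 30 mitosis members. The erythroid mean was lower and the handling-stress mean higher in 17 of 17 patients. The counts with these covariates are thus read at a point outside the data.

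In the BM, haemoglobin genes and DNTT were among the genes with the largest differences from PB. HBB was higher by 3.61 ± 0.40 (log2, SE, n = 19) in 18 of 19 patients, HBD, the delta chain, by 2.23 ± 0.31 and HBM, a further globin, by 1.63 ± 0.23. DNTT, the DNA polymerase of lymphoid precursors, was higher by 2.10 ± 0.34 in 19 of 19 patients. S100A8, an abundant protein of granulocytes and monocytes, was higher by 1.70 ± 0.35. Of the genes tested, 1276 differed (limma, adjusted p under 0.05), 800 higher in BM and 476 lower, of which 25 at least doubled and 2 at least halved. With each array centred on its median the split was 687 higher and 679 lower.

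The erythroid list had 6 of 7 members higher (adjusted p = 9.74e-09), including CA1, a carbonic anhydrase of red cells, at 1.28 ± 0.20 and SLC4A1, the anion exchanger of the red cell membrane, at 1.27 ± 0.23. Of 6 granulocyte and precursor markers 3 were higher (adjusted p = 0.000375), with LCN2, an iron-binding granule protein, at 0.82 ± 0.18 and DEFA4, a defensin, at 0.83 ± 0.19. Of 7 platelet and megakaryocyte markers 3 were higher (adjusted p = 0.000408), with the integrin ITGA2B at 0.69 ± 0.12 and PPBP, a platelet chemokine, at 1.17 ± 0.31. Adjusted over each list alone the counts were 6, 5 and 4. With an estimated correlation the adjusted p values were 0.106, 0.225 and 0.106, so these calls are lost, as are all 11 list calls in BM against PB. The erythroid mean was higher by 1.73 ± 1.17 (SD) in 4 patients without poly-A controls and by 1.47 ± 0.84 (SD) in the 15 others, and the granulocyte mean by 1.23 ± 1.24 and 0.46 ± 0.51 (SD).

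Among the cell division genes, 22 of 30 G2/M members rose in BM and none fell (adjusted p = 2.84e-20, and 0.106 with an estimated correlation). Adjusted over the list alone 28 rose. MELK was higher by 1.24 ± 0.16, TOP2A by 1.15 ± 0.18 and CDC20, an activator of the anaphase-promoting complex, by 0.97 ± 0.16. In the replication list 8 of 26 rose and 1 fell (adjusted p = 1.47e-06, and 0.154 with an estimated correlation), and 11 rose and 1 fell when adjusted over the list alone. TYMS was higher by 1.81 ± 0.26 and RRM2 by 1.42 ± 0.20. The G2/M list mean was higher in 19 of 19 patients, by 0.60 ± 0.49 (SD, n = 19). It was higher by 0.87 ± 0.63 (SD) in 4 patients without poly-A controls and by 0.53 ± 0.45 (SD) in the 15 others. For the replication list these values were 0.52 ± 0.36 and 0.28 ± 0.27 (SD).

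BCR response genes rose in part. Of 22 members 9 rose and 1 fell (adjusted p = 1.35e-06, and 0.106 with an estimated correlation), and 11 rose and 1 fell when adjusted over the list alone. EGR3, an early response transcription factor, was higher by 0.97 ± 0.13, its co-repressor NAB2 by 0.52 ± 0.09, and DUSP6, a phosphatase of the ERK kinases, by 1.13 ± 0.22. RGS1 was at 0.49 ± 0.41 (adjusted p = 0.512) and did not pass. The list mean was higher by 0.76 ± 0.76 (SD) in 4 patients without poly-A controls and by 0.31 ± 0.24 (SD) in the 15 others. The monocyte mean was higher by 0.91 ± 0.70 (SD) in the same 4 patients and by 0.14 ± 0.48 (SD) in the 15 others. Of 12 monocyte markers 2 were higher, 3 when adjusted over the list alone, and the list did not pass (adjusted p = 0.283). Handling-stress genes were higher too, 6 of 18 of them, 10 when adjusted over the list alone (adjusted p = 2.57e-05, and 0.322 with an estimated correlation). FOSB was higher by 2.45 ± 0.33 and FOS by 1.55 ± 0.33. The list mean was higher by 1.00 ± 1.19 (SD) in the 4 patients and by 0.34 ± 0.34 (SD) in the 15 others. NF-κB targets did not pass (3 of 26 higher, 2 lower, adjusted p = 0.379), and 4 were higher and 3 lower when adjusted over the list alone.

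Lower in BM were RHOB, a small GTPase, which fell by 1.30 ± 0.21, ARRDC3, which fell by 1.21 ± 0.19, CPNE5, a calcium-dependent membrane protein, which fell by 0.61 ± 0.09, CRIP1, a LIM domain protein, which fell by 0.56 ± 0.11, and ANXA2, an annexin, which fell by 0.51 ± 0.08. Of 18 interferon response genes 2 fell (adjusted p = 0.0328), and 4 fell when adjusted over the list alone. Of 19 oxidative phosphorylation genes 3 fell (adjusted p = 0.00312), also when adjusted over the list alone. With an estimated correlation the adjusted p values were 0.461 and 0.434. ISG15, a ubiquitin-like protein induced by interferon, fell by 0.21 ± 0.06 and SDHC, a subunit of succinate dehydrogenase, fell by 0.24 ± 0.08. Of 19 MYC target genes 2 rose (adjusted p = 0.0328) and of 18 genes of the unfolded protein response 2 rose (adjusted p = 0.0313), with 3 each when adjusted over the list alone. Their adjusted p was 0.434 each with an estimated correlation. Leaving out each patient in turn gave 1 to 4 interferon genes and 1 to 3 genes of the unfolded protein response. HERPUD1, a protein of endoplasmic reticulum quality control, was higher by 0.33 ± 0.06. Of 7 T cell markers 0 passed in limma and 1 had an unadjusted p under 0.05 (list mean -0.09 ± 0.30, SD, n = 19). The 3' to 5' ratio of ACTB was higher in BM by 0.18 ± 0.36 (SD; permutation p = 0.0422, adjusted p = 0.253). Without the patient block 64 genes were called, and 321 in the 12 patients with all compartments. With covariates the count was 816 for the 3' to 5' ratio, 810 for handling stress, 546 for T cell and monocyte markers and 0 for erythroid and granulocyte markers (1193 genes then had an unadjusted p under 0.05 in limma). Erythroid and handling-stress means were higher in 18 of 19 patients each, so the counts with these covariates are read at the edge of the data.

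**Figure D2:**
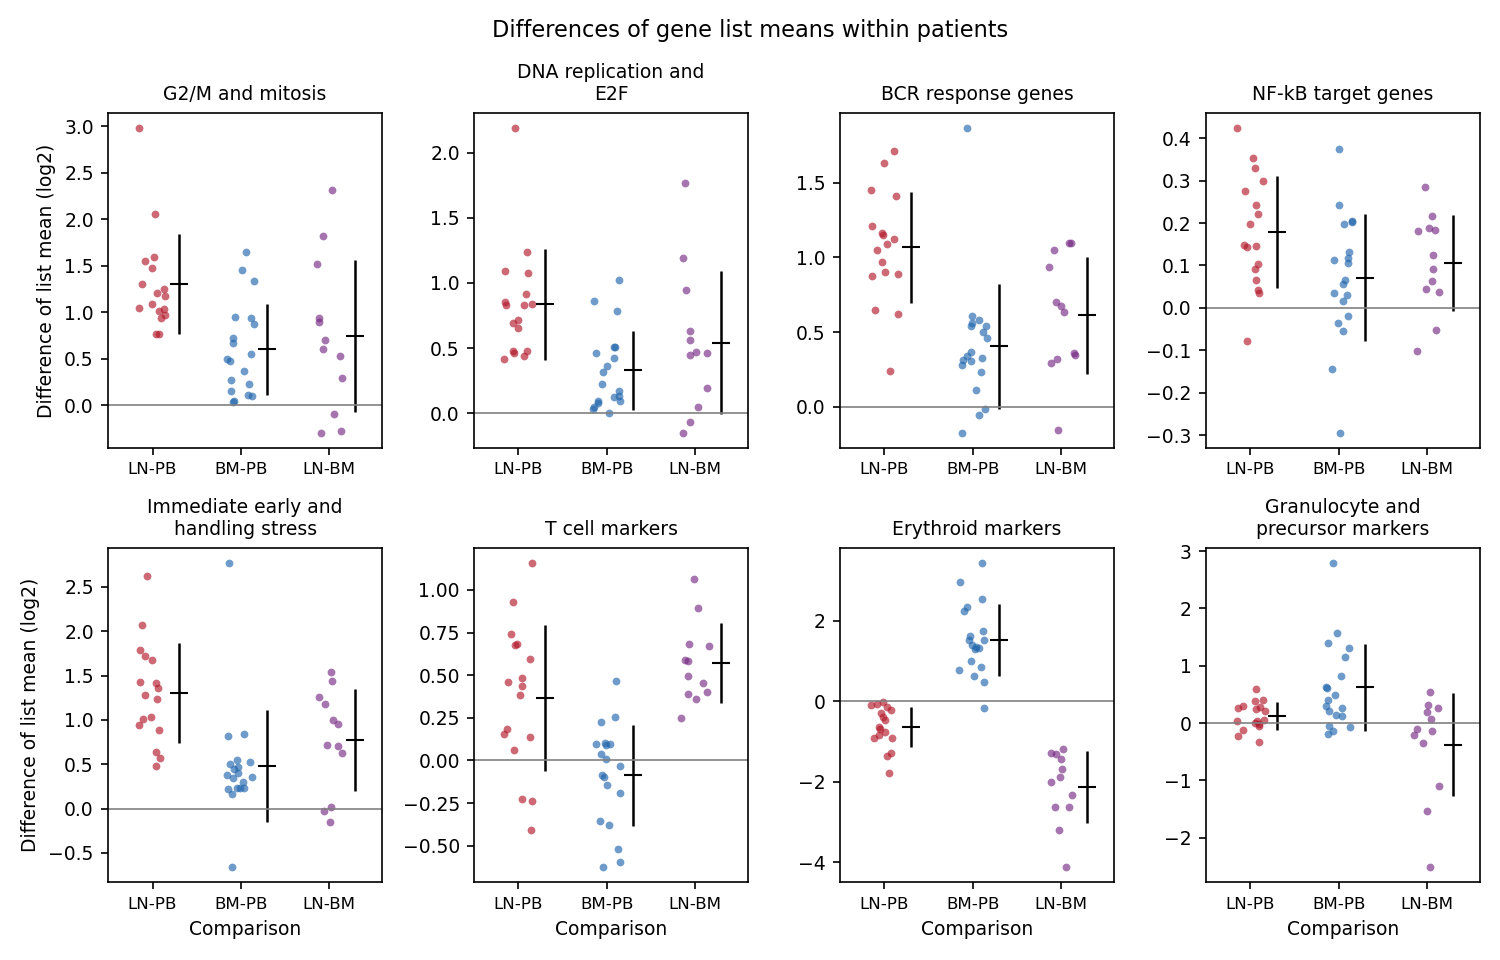
Difference of the mean of 8 gene lists within patients, in log2 units (y axis), for LN minus PB (17 patients), BM minus PB (19) and LN minus BM (12) (x axis). Each point is 1 patient, and the bar beside the points gives the mean ± SD. The G2/M list lies above 0 in 17 of 17 patients for LN minus PB, in 19 of 19 for BM minus PB and in 9 of 12 for LN minus BM.

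Measured directly in the 12 patients with both samples, RGS1 had the largest increase and HBB the largest decrease in LN against BM. RGS1 was higher in LN by 4.32 ± 0.53 (log2, SE, n = 12), RGS2 by 2.28 ± 0.37, DUSP1 by 1.86 ± 0.27 and CD69 by 1.35 ± 0.15, each in 12 of 12 patients. CR2 was higher by 1.43 ± 0.17 and LY9, a receptor of the SLAM family, by 1.44 ± 0.20. FABP5, a fatty acid binding protein, was higher by 1.37 ± 0.26. HBB fell by 6.04 ± 0.38 and HBD fell by 2.87 ± 0.38. DNTT fell by 2.04 ± 0.38, and BACH2, a repressor of plasma cell differentiation, fell by 1.24 ± 0.12 in 12 of 12 patients. In all 1459 genes differed (limma, adjusted p under 0.05), 655 higher in LN and 804 lower, of which 36 at least doubled and 14 at least halved.

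The G2/M list had 21 of 30 members higher in LN than in BM and none lower (adjusted p = 1.87e-14, and 0.222 with an estimated correlation). Adjusted over the list alone, 29 were higher and 1 lower. The count over all genes was 10 without the patient whose LN array stood apart, with a list mean of 0.60 against 0.74, and ranged from 5 to 27 when each patient was left out in turn. It was 11 with a trended and robust variance and 7 without the limit on dim genes, while 30 of 30 members had an unadjusted p under 0.05 in limma without that patient and under both of these settings. Its mean was higher by 0.74 ± 0.82 (SD, n = 12) in 9 of 12 patients (permutation test, adjusted p = 0.0178). This difference was 0.04 ± 0.57 (SD) in 3 patients without poly-A controls and 0.98 ± 0.77 (SD) in the 9 others. In the same patients the monocyte mean was -1.77 ± 0.98 in the 3 and -0.15 ± 0.68 (SD) in the 9, and the granulocyte mean -1.47 ± 1.09 and -0.02 ± 0.47 (SD). The replication list had 10 of 26 members higher and none lower (adjusted p = 1.88e-10, and 0.214 with an estimated correlation), and 18 when adjusted over the list alone. Leaving out each patient in turn gave 6 to 12. Its mean difference was 0.12 ± 0.32 (SD) in the 3 patients and 0.68 ± 0.55 (SD) in the 9 others. BCR response genes were higher for 8 of 22 members (adjusted p = 5.51e-06, and 0.109 with an estimated correlation), and for 10 when adjusted over the list alone. Their mean difference was 0.18 ± 0.29 (SD) in the 3 patients and 0.76 ± 0.31 (SD) in the 9 others. Handling-stress genes were higher for 9 of 18 members (adjusted p = 2.94e-07, and 0.177 with an estimated correlation), and for 11 when adjusted over the list alone. Their means were 0.19 ± 0.45 (SD) and 0.97 ± 0.48 (SD) in these patients. NF-κB targets did not pass (adjusted p = 0.166), with 4 of 26 higher and 2 lower, and 6 and 3 when adjusted over the list alone.

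T cell markers were higher in LN for 4 of 7 members (adjusted p = 6.53e-06), and this was the one list call that held with an estimated correlation (adjusted p = 0.0432). Adjusted over the list alone 5 were higher. CD3D was higher by 1.16 ± 0.11 in 12 of 12 patients. Erythroid markers were lower for 6 of 7 members (adjusted p = 1.54e-09, and 0.0949 with an estimated correlation), and for 7 when adjusted over the list alone. In patients without and with poly-A controls (n = 3 and 9) the T cell means were 0.47 ± 0.19 and 0.60 ± 0.25 (SD), and the erythroid means -2.72 ± 1.35 and -1.94 ± 0.68 (SD).

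A further 8 lists passed in LN against BM, and none of these calls held with an estimated correlation. Higher in LN were 6 of 19 MYC targets (adjusted p = 2.85e-05, and 0.242 with an estimated correlation), 6 of 17 glycolysis genes (5.13e-05 and 0.178 in the same order), 5 of 19 oxidative phosphorylation genes (0.00019 and 0.375) and 2 of 7 NK and cytotoxic markers (0.000806 and 0.178). Without the patient whose LN array stood apart, 0 oxidative phosphorylation genes were called by limma (7 had an unadjusted p under 0.05) and 1 NK marker, and leaving out each patient in turn gave 1 to 4 NK markers. No oxidative phosphorylation gene was called either without the limit on dim genes or with a trended and robust variance (8 had an unadjusted p under 0.05 in both). RRP12 was higher by 1.53 ± 0.32. Of 18 interferon response genes 4 were higher and 1 lower (adjusted p = 0.0182, and 0.355 with an estimated correlation). Of 3 tissue macrophage markers 0 passed in limma and 2 had an unadjusted p under 0.05, while the list passed (adjusted p = 0.0366, and 0.177 with an estimated correlation). Of 7 platelet markers 2 were lower (adjusted p = 0.00273, and 0.177 with an estimated correlation), PF4, a platelet chemokine, at -1.26 ± 0.24 and PPBP at -1.93 ± 0.32. Of 15 B cell and CLL markers 3 were lower (adjusted p = 0.0491, and 0.369 with an estimated correlation). Adjusted over each list alone, 7 MYC targets, 7 glycolysis genes, 6 oxidative phosphorylation genes, 4 NK markers, 5 interferon genes and 1 macrophage marker were higher. On the same adjustment 1 glycolysis gene, 1 interferon gene, 4 platelet markers and 4 B cell and CLL markers were lower. Without the patient block 79 genes were called, and 2930 or 2686 when all 24 patients entered with a fixed or a random block. The count was 942 to 1439 when each patient was left out in turn, and the lowest values were 942, 962, 982 and 1005. With covariates the limma count was 1 for T cell and monocyte markers, 2 for handling stress and 0 for erythroid and granulocyte markers (1438, 1166 and 561 genes with an unadjusted p under 0.05). The mean of the G2/M list, 0.74 without covariates, was then 1.98, 0.55 and 0.57, and that of the BCR response list, 0.61 without them, was 1.01, 0.24 and 0.06. These values are read at no covariate difference. T cell markers were higher in 12 of 12 patients, erythroid markers in 0 of 12 and handling-stress genes in 10 of 12. That point thus lies outside or near the edge of the data. Lost calls and changed means here do not show that the covariates explain the differences.

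The differences from PB in LN and in BM were compared gene by gene. Across 13034 genes, which are not independent replicates, they correlated with r = 0.489 and a covariance of 0.0212. The PB arrays are shared by these comparisons, and 100 simulations without any effect gave a mean r of 0.338 (highest 0.512) and a mean covariance of 0.00289 (highest 0.00546). The observed r lay below the highest simulated r, while the observed covariance lay above every simulated covariance. With separate patients, 5 for LN and 7 for BM, r was 0.254 and the covariance 0.0136. Means over fewer patients are noisier, which alone can lower r, so 0.254 is not directly comparable with 0.489. Higher in both compartments were 401 genes, lower in both were 243, and opposite directions were called for 27. Because the PB arrays are shared, these overlaps have no simple value under no effect and were not tested.

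**Figure D3:**
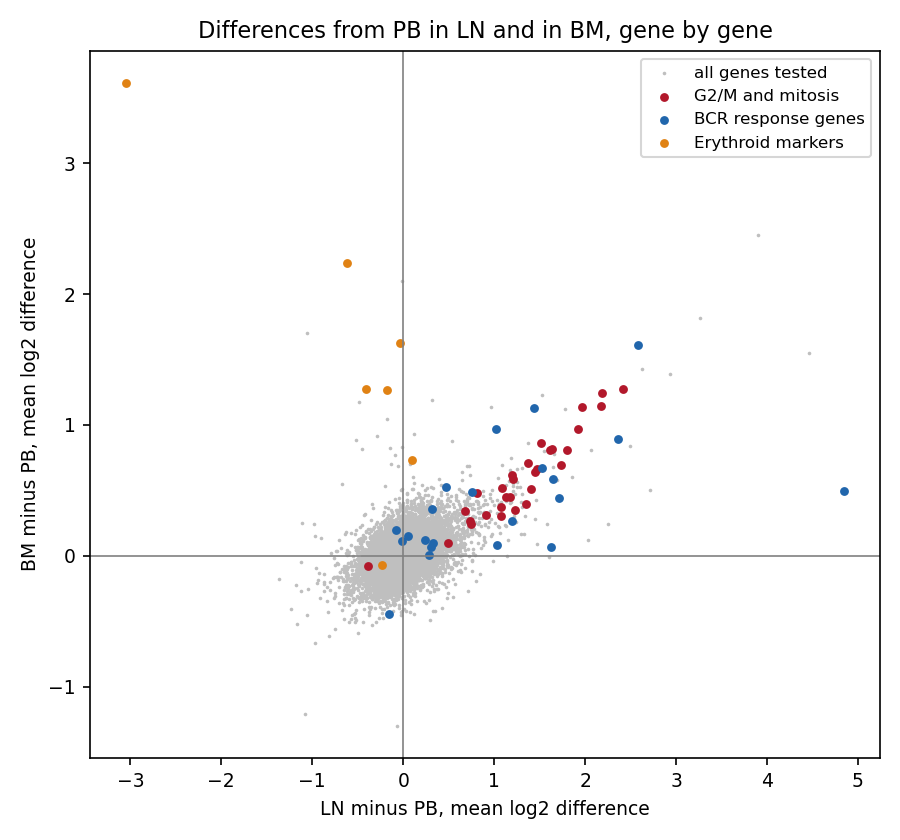
Mean log2 difference from PB in LN (x axis, 17 patients) and in BM (y axis, 19 patients) for all genes tested except sex-linked markers and receptor segments (grey), with 3 gene lists in colour. HBB lies at -3.04 in LN and 3.61 in BM, while TOP2A lies at 2.18 and 1.15.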

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

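The differences below passed a test of LN against BM in the same 12 patients, which is the difference between the changes of LN and BM against the same PB. The test of marrow precursors, the choice of genes with opposite directions and the reading of a covariate that lies on 1 side of 0 were chosen after the results were seen.

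Of the 25 gene list means, 15 changed differently in LN and in BM (two-sided sign-flip permutation test, adjusted p under 0.05). Given as LN minus BM on the log2 scale, these were the BCR response genes at 0.61 (higher in 11 of 12 patients), MYC targets at 0.33 (11 of 12), glycolysis and hypoxia at 0.27 (11 of 12) and T cell markers at 0.57 (12 of 12), each with an adjusted p of 0.00504. Handling-stress genes were at 0.77 and DNA replication genes at 0.54 (10 of 12 each, adjusted p = 0.0113). G2/M genes were at 0.74 (9 of 12) and tissue macrophage markers at 0.36 (10 of 12, adjusted p = 0.0178 each). NK and cytotoxic markers were at 0.37 (10 of 12, adjusted p = 0.0169) and NF-κB targets at 0.11 (10 of 12, adjusted p = 0.0220). Further differences were 0.16 for oxidative phosphorylation (10 of 12, adjusted p = 0.0394) and 0.076 for the unfolded protein response (9 of 12, adjusted p = 0.0410). Camera did not pass 2 of these lists: NF-κB targets (adjusted p = 0.166, and 0.358 with an estimated correlation) and the unfolded protein response (0.133 and 0.391), where 0 of 18 members were higher and 1 lower in limma. Erythroid markers were at -2.13 (higher in 0 of 12, adjusted p = 0.00504), platelet markers at -0.66 (1 of 12, adjusted p = 0.00504) and B cell and CLL markers at -0.14 (1 of 12, adjusted p = 0.01004).

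Named genes called in opposite directions against PB in LN and BM had these LN minus BM values (limma). They were picked for those opposite directions in largely the same patients, so a difference was built in and its p adds no evidence. HBB was at -6.04 (adjusted p = 5.22e-07), HBD at -2.87 (adjusted p = 0.000566), CA1 at -1.77 (adjusted p = 0.00123), PPBP at -1.93 (adjusted p = 0.00237), PF4 at -1.26 (adjusted p = 0.00588) and BACH2 at -1.24 (adjusted p = 6.21e-05).

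The counts of called genes were set against 100 assignments of the direction of each patient's pair, the real one included. In each comparison 1 of 100 reached the real count, which was the real assignment itself. The highest of the others called 4 genes against 3341 for LN and PB, 2 against 1276 for BM and PB, and 1 against 1459 for LN and BM. No other assignment thus came near the real count. With 100 assignments 1 of 100 is the smallest share that can be reached, so chance is not excluded. The counts bear on the total of called genes and not on any single gene or list.

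The rise of the mitosis list in LN was weighed against other cells in the sample and against RNA quality. At no difference in T cell and monocyte markers the list was still higher by 1.247 (95% interval 0.805 to 1.69), against 1.31 without this term. At no difference in the 3' to 5' ratio it was higher by 1.322 (95% interval 1.03 to 1.61). Along these lines the measured differences in markers and ratio thus do not account for the rise. Only 7 T cell markers were tested, and noise in a covariate flattens its line, so neither explanation is excluded. More frequent division of CLL cells in the LN and dividing cells of other kinds both remain open and were not told apart. It is not given whether cells were sorted.

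The rise of the BCR response list in LN was weighed against a response to sample handling: at no difference in handling-stress genes the line through the patients put the list at 0.7841 (95% interval 0.298 to 1.27), against 1.07 ± 0.37 (SD, n = 17) without this term. Before the data were examined, an interval above 0 was to count against handling, but the handling list was higher in 17 of 17 patients, so that point lies outside the data and anything all LN samples share stays in this value. With this term 0 of 22 members were called by limma and 9 had an unadjusted p under 0.05, at a wider interval because the point lies outside the data. Across the 17 patients the lists had a Pearson r of 0.328 (permutation p = 0.199, adjusted p = 0.331 over 5 relations) and a Spearman rho of 0.277 (p = 0.281), with r = 0.0436 without the 2 farthest patients and -0.0479 within the 13 patients with poly-A controls. Handling and BCR signalling cannot be told apart here, since tissue origin and sampling go together.

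The rise of the mitosis list in BM was weighed against dividing blood cell precursors: at no difference in erythroid and granulocyte markers the list stood at 0.4934 (95% interval 0.112 to 0.875), against 0.60 ± 0.49 (SD, n = 19) without these terms. With them 0 of 30 members were called by limma and 14 had an unadjusted p under 0.05. The list followed the granulocyte markers (Pearson r = 0.648, permutation p = 0.00267, adjusted p = 0.0134 over 5 relations, Spearman rho 0.535 with p = 0.0195), with r = 0.469 without the 2 farthest patients and 0.439 within the 15 patients with poly-A controls. No relation to the erythroid markers passed (Pearson r = 0.239, permutation p = 0.325, adjusted p = 0.406, Spearman rho 0.163 with p = 0.504). Within the 15 patients with poly-A controls that r was 0.0415. Erythroid markers were higher in 18 of 19 patients (HBB by 3.61), so the point of no difference lies at the edge of the data. Precursors may therefore contribute, and they cannot be told apart from dividing CLL cells as the source, as no sort that would remove them is given.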

How the results depend on the processing

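The alternatives with erythroid and granulocyte covariates, with poly-A control patients only or without the patient whose LN array stood apart, and the counts of list members when each patient is left out, were chosen after the data had been seen. The planned quantile normalization changes nothing, since all arrays hold the same values, and the alternatives on repeat PB arrays and on patients with all compartments leave LN against BM as it is, so these gave no value. Unless stated, the cause of a change was not tested.

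Counts of genes were within 1.5 times those reported under the alternatives not named below. Testing every probe set on its own gave 7176 probe sets for LN against PB, 2197 for BM against PB and 2571 for LN against BM, out of more features. The patient block mattered: without the pairing 1050, 64 and 79 genes were called, and all of them had also been called with it. A block over 3 groups gave 2930 for LN against BM and a random block 2686, with more patients. Patients with all 3 compartments gave 2223 for LN against PB and 321 for BM against PB, with fewer patients. T cell and monocyte covariates gave 1107, 546 and 1 genes, the handling covariate 75, 810 and 2, and the 3' to 5' ratio 816 for BM against PB. Erythroid and granulocyte covariates gave 382, 0 and 0 genes in limma, with 2393, 1193 and 561 at an unadjusted p under 0.05. Where a covariate lay on 1 side of 0 in nearly all patients, its count is read outside or at the edge of the data. A lost call then does not show that the covariate explains the difference. Leaving out 1 patient at a time gave 2984 to 3258, 1008 to 1376 and 942 to 1439 genes. For LN against BM, leaving out either of 2 patients gave 942 or 962, the only values beyond 1.5 times, with 982 and 1005 next.

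Among list tests, an estimated correlation ended 5 of 8 calls in LN against PB, among them that of DNA replication (adjusted p = 0.112). In BM against PB it ended all 11 calls, among them BCR response (0.1061), G2/M (0.1061), replication (0.1544) and erythroid markers (0.1061). In LN against BM it ended 13 of 14, among them BCR response (0.1088), G2/M (0.2216), replication (0.2137) and erythroid markers (0.09486). In LN against PB, the NF-κB targets passed without the limit on dim genes (0.00738), without the floor (0.04898) and with T cell and monocyte covariates (0.04966), and erythroid markers passed without that limit (0.02539) and without the floor (0.03945). Of 240 further list tests under alternatives 205 stayed on the same side of the threshold, 30 lost and 5 gained a call, and 0 reversed. The correlation of LN and BM effects was 0.254 in separate patients, with noisier means from fewer patients, and 0.464 without the limit on dim genes.

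Of 3393 values of named genes under 18 alternatives, 2846 kept direction and side, 508 fell short of the threshold, 16 passed it and 23 reversed, as log2 values. In LN against PB these were CST7 with T cell and monocyte covariates (-0.023), NR4A2 (-0.36), LYZ (0.11), MAML2 (-0.053) and DDIT3 (-0.34) with the handling covariate, and CD200 (-0.053), FCN1 (0.031), HBD (0.14) and CA1 (0.20) with erythroid and granulocyte covariates. With the latter in BM against PB they were HBD (-0.25), S100A8 (-0.18), HBM (-0.057), CA1 (-0.11), SLC4A1 (-0.27), CAMP (-0.34), PF4 (-0.10) and PPBP (-0.55), and in LN against BM NR4A2 (-1.03), HBD (0.93), DNTT (0.37), CA1 (0.11) and HBM (1.49). FOSB in LN against BM reversed with the handling covariate (-0.58). HBD, CA1, HBM, SLC4A1 and CAMP are members of the erythroid and granulocyte lists, and NR4A2 and FOSB of the handling list, so their own values enter the correction by their list. Genes near the floor have little signal over background, so their differences are understated.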

Other observations

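Of the lists not yet described, none passed camera in LN against PB. Of 7 tested Notch pathway genes 3 rose and 1 fell (adjusted p = 0.174), and 5 rose and 1 fell when adjusted over the list alone, with the receptor NOTCH2 lower by a log2 value of -0.63 ± 0.08 in 17 of 17 patients and NOTCH1 at 0.35 ± 0.09. Of 17 genes of T cell crosstalk 2 rose and 1 fell (adjusted p = 0.288). IL21R, the receptor of a follicular helper T cell cytokine, was higher by 0.68 ± 0.10 and IL4R lower by -0.41 ± 0.11. Of 18 interferon response genes 2 rose and 1 fell (adjusted p = 0.555), with OAS3, an antiviral enzyme, at 0.67 ± 0.12. Of 19 oxidative phosphorylation genes 5 rose (adjusted p = 0.120), with COX5A, a subunit of cytochrome oxidase, at 0.31 ± 0.07. For these last 3 lists, and for the 6 lists of other cell types that follow, the counts were the same when adjusted over the list alone.

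Among other cell types in LN against PB, 1 of 7 stromal and follicular dendritic cell markers rose, VCAM1, an adhesion molecule, at 0.65 ± 0.12 (list adjusted p = 0.122), and leaving out each patient in turn gave 1 or 2. Of 3 tissue macrophage markers 2 rose (adjusted p = 0.120), with the mannose receptor MRC1 at 0.52 ± 0.17, and leaving out each patient in turn gave 0 to 2. Of 7 NK and cytotoxic markers 2 rose (adjusted p = 0.403), with the chemokine CCL5 at 0.49 ± 0.13, and leaving out each patient in turn gave 1 or 2. Of 6 granulocyte markers 2 rose (adjusted p = 0.296), with CAMP at 0.54 ± 0.14. Of 7 platelet markers 2 fell (adjusted p = 0.307), with PF4 at -0.45 ± 0.13. Of 10 plasma cell markers 1 rose and 1 fell (adjusted p = 0.336), with TNFRSF17, a survival receptor of plasma cells, at 0.55 ± 0.12, and leaving out each patient in turn gave 1 or 2 that rose and 0 to 2 that fell.

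The sign-flip permutation test of list means does not compare a list with other genes, and it passed some lists that camera did not. In LN against PB it did so for Notch (0.12, higher in 14 of 17 patients, adjusted p = 0.00836), tissue macrophage (0.34, 13 of 17, 0.00434), stromal (0.23, 13 of 17, 0.00463), platelet (-0.17, 4 of 17, 0.0380), BCL2 family (-0.11, 2 of 17, 0.000417), B cell and CLL (-0.087, 5 of 17, 0.0417) and BCR pathway genes (0.086, 13 of 17, 0.0243). In BM against PB it did so for BCR pathway (0.058, 16 of 19, 0.00281), BCL2 family (-0.079, 3 of 19, 0.00100), Notch (0.10, 15 of 19, 0.00463) and glycolysis genes (0.066, 14 of 19, 0.0367). The interferon list passed camera and not this test in BM against PB (-0.061, adjusted p = 0.214) and in LN against BM (0.14, 0.0502).

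The mean LN minus BM difference was compared between 3 patients without poly-A controls, where it was lower, and the 9 others. An exact permutation test over 220 splits gave p = 0.0273 for BCR response genes, 0.0364 for handling stress, 0.0864 for mitosis and 0.123 for replication. Adjusted over these 4 lists, chosen after the data had been seen, the values were 0.0727, 0.0727, 0.115 and 0.123, and none passed. The monocyte mean (-1.77 in the 3 patients, -0.15 in the 9) and the granulocyte mean (-1.47 and -0.02) were also lower in the 3 patients, which was not tested.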
